A study of Mus musculus with 12 samples.

How the data were processed

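Messenger RNA was measured in mouse embryonic stem (ES) cells of 4 genotypes with 3 biological replicates each, 12 arrays in all. Per the labels' protocols, RNA was extracted with Trizol, the undifferentiated state was judged by colony morphology, and a commercial provider did the labelling, the hybridisation to Affymetrix Mouse 430_2.0 arrays and the primary analysis. Per the labels, the double deficient line was made by targeting Ring1B in Eed deficient cells.

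The deposited values are intensity values, which the authors made with MAS5, per the submitters' processing notes. The version of MAS5, its settings, the scan dates and the cell passages are not given in the sources used here. The values are on a linear scale, and the trimmed mean of each array, with 2% left off at each end, was 100, so the arrays had already been scaled to a common level. Detection calls were not analysed here. Array medians ran from 19.07 to 28.01, and their ratio of 1.47 lay under the limit set for further normalization, so none was applied. Between 22.8% and 24.9% of probe sets had a signal above 100. The number of arrays limits the precision.

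The value table held 45101 probe sets, of which 64 were array controls. Of the other 45037, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were not in that annotation. Of the probe sets with 1 symbol, 34754 had an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Genes were named only from probe sets with 1 symbol, 18194 genes in all. A probe set was kept if at least 3 of the 12 arrays lay above that array's 40th percentile, which left 30027 probe sets. For each gene, the probe set with the highest mean log2 value was tested, 13984 genes in all.

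Signals were turned into log2 values after adding 5, the rounded median of the arrays' 20th percentiles. Fold changes are on this scale, and for genes near the background they are smaller than the ratio of signals. Levels are given as mean signal ± SD over the 3 arrays of a genotype. A linear model with 1 mean per genotype was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. Adjusted p values come from this limma model with Benjamini-Hochberg adjustment over the 13984 genes, and a gene was called at an adjusted p under 0.05. The contrasts were each mutant against wild type, the double deficient genotype against each single mutant, Eed deficient against Ring1B deficient, and the interaction, which is the change from Eed deficient to double deficient minus the change from wild type to Ring1B deficient. A further count took the genes called the same way in the double deficient genotype against each of the other 3 genotypes. Overlaps of calls between contrasts that share arrays were set beside 50 simulations without effects and beside the count for independent lists.

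The contrasts, the filter, the gene lists, the rule for naming genes and the alternative settings were chosen before the data were examined. The lists, with the number of genes tested, were Hox cluster genes (26), pluripotency genes (28), primitive and visceral endoderm genes (24), mesoderm and primitive streak genes (28), neuroectoderm genes (25), trophoblast genes (20), Polycomb complex members (31), germline genes (26), imprinted genes (24), cyclin-dependent kinase inhibitors (8), secreted signalling ligands (39), fibroblast and feeder cell markers (25), 2-cell-stage genes (5), DNA methylation and retroelement silencing genes (21) and housekeeping genes (12). A list of retroelement transcripts had 0 tested genes and was not analysed. Lists were tested against all other genes with camera at its preset correlation of 0.01 and again with an estimated correlation. Whether the genes of a list moved 1 way, without a comparison with other genes, was tested with fry. A list is described as called or not called by camera, and fry is named where its values are given. Each test was adjusted over the lists. List members were also adjusted over the list alone. Lists of macrophage, ERK target and ribosome biogenesis genes were added later for the tests of other cell types and growth state.

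Genes are named by rule. Rnf2 and Eed come with every probe set. Each contrast names from the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between the groups and whose higher group mean lies above the median of the tested genes. It also names from up to 4 members of each list by size of change, and Pou5f1, Nanog, Sox2, Gata4, Gata6, Cdx2, Hand1, Ezh2, Suz12, Ring1 and Bmi1. The gene T was on this list and was not analysed here. The set beyond all other genotypes names from the 12 genes with the largest smallest change, and the interaction from the 8 largest of each sign. Genes outside the rule are identified as chosen after their values were seen.

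The alternative settings were quantile normalization, median centring, an added value of 1 or 10 in place of 5, no filter, a filter at the 60th percentile, the mean of all probe sets per gene, leaving out probe sets marked as matching several transcripts, no intensity trend, array weights, a fit of the compared groups alone, a replicate block, a 2-fold minimum, an estimated correlation for the lists and leaving out each array. Added after the data were seen were a fit without the 4 arrays numbered 2, and fits without genes at least 1.5-fold (319 genes) or 2-fold (98 genes) higher in Eed deficient replicate 3 than in each other Eed deficient array.

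The labels number the replicates of every genotype from 1 to 3, and nothing in them says that a number marks a shared culture day. Deviations of same-numbered arrays from their group means correlated at r = 0.399, 0.614 and 0.179 between the Eed deficient and the Ring1B deficient arrays, across genes, and each of these 6 arrays correlated best with its own number. This contrast alone met the limit of 0.1 for every pair, so its count with the replicate number as a block is given beside its main count. The values printed for its genes and lists come from the fit without the block.

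The fit was tested on simulated data, drawn independently for each gene and array with the gene's real spread. Among 13984 genes, 100 were changed 2-fold and 100 changed 4-fold in the double deficient group, in 10 simulations. For the double deficient genotype against wild type it recovered 59.6% of the 2-fold and 94.1% of the 4-fold changes, with 4.28% false calls. Against Eed deficient cells the shares were 61.7%, 94.2% and 4.58%, and against Ring1B deficient cells 57.7%, 94.7% and 6.07%. For the interaction they were 30.1%, 80.3% and 5.95%. The mesoderm and primitive streak genes were also shifted in the simulated double deficient group and were not counted as false calls. The simulated arrays lacked the deviations that same-numbered real arrays share, so these shares of false calls need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.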

Results

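The data were signals from 12 Affymetrix arrays of mouse ES cells that were wild type, Ring1B deficient, Eed deficient or deficient for both, with 3 arrays per genotype. The labels describe no second line of any genotype. Standard errors and adjusted p values of the limma model rest on the spread between arrays of a genotype. Every contrast therefore also holds any differences between lines. Ring1B, encoded by Rnf2, is the core ubiquitin ligase of the Polycomb complex PRC1, and Eed is a core subunit of the histone methyltransferase complex PRC2. Both complexes keep developmental genes low in ES cells. The array medians ran from 19.07 to 28.01 in signal units, with a trimmed mean of 100 in every array. Correlations of log2 signals between replicates ran from 0.963 to 0.984 across genes, which are not independent replicates. The first principal component of the 12 arrays held 42.4% of the variance and the second 16.9%.

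The targeted genes were read first. The brighter of the Eed probe sets gave 1428 ± 159 in wild type, 1642 ± 283 in Ring1B deficient, 37.8 ± 13.1 in Eed deficient and 71.2 ± 21.0 in double deficient cells (SD, n = 3). The other Eed probe set stayed between 12.7 and 18.0 in all 4 genotypes, near the background. The brightest Rnf2 probe set gave 851 ± 124 in wild type, 468 ± 65.7 in Ring1B deficient, 779 ± 168 in Eed deficient and 383 ± 18.8 in double deficient cells. The next gave 632 ± 74.6, 330 ± 23.1, 531 ± 106 and 275 ± 22.6 in the same order. A weaker Rnf2 probe set went the other way in Ring1B deficient cells, with 29.9 ± 7.02, 60.2 ± 8.27, 22.3 ± 3.23 and 38.5 ± 3.8. The other 2 Rnf2 probe sets were the weakest, with genotype means from 2.06 to 5.73 and from 12.3 to 19.4. The deleted parts of the genes are not given in the sources used here. A probe set outside a deleted part reads the remaining transcript, so the remaining Rnf2 signal does not measure Ring1B protein.

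**Figure D1:**
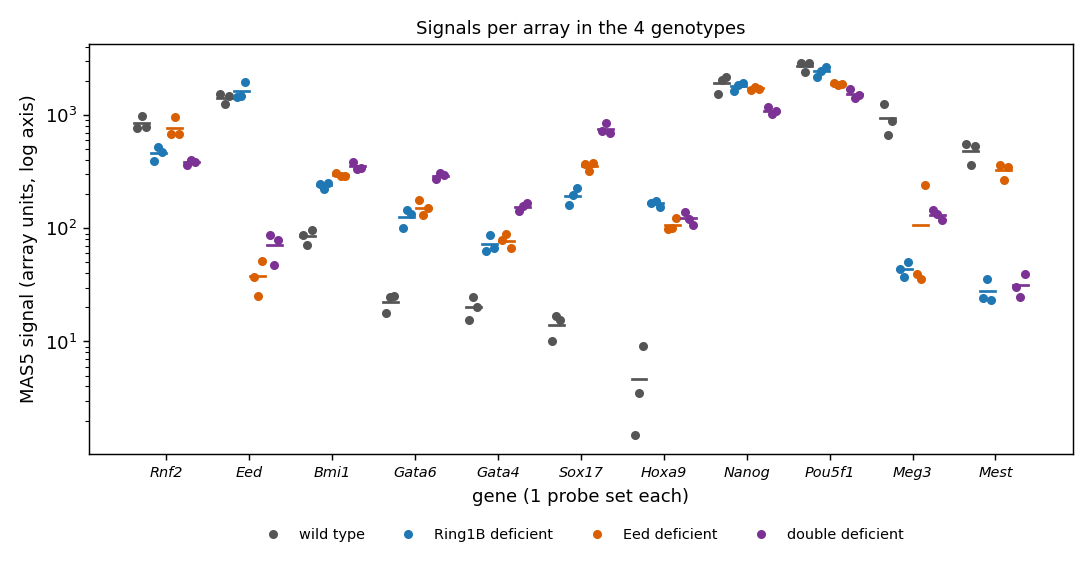
MAS5 signal (log axis) of 11 genes in each of the 12 arrays, with points for arrays and bars for the mean of 3 arrays per genotype. Gata6 rose from 22.6 in wild type to 127, 153 and 293 in the Ring1B, Eed and double deficient cells, and Eed fell from 1428 in wild type to 37.8 in Eed deficient cells.

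Ring1B deficient cells were compared with wild type to find which genes change when PRC1 lacks this subunit. Endoderm regulators rose. Sox17, a transcription factor of endoderm, went from 14.1 ± 3.46 to 194 ± 33.2 (SD, n = 3), a log2 change of 3.39 (SE 0.18). Gata6 and Gata4, which direct primitive endoderm, rose from 22.6 ± 4.14 to 127 ± 22.8 and from 20.1 ± 4.59 to 72.5 ± 13.3, log2 changes of 2.26 and 1.63. Hoxa9, a gene of the posterior body, went from 4.69 ± 3.93, near the background, to 166 ± 10.3. Bmi1, itself a PRC1 subunit, rose from 85.4 ± 13.3 to 240 ± 15.8 (log2 change 1.45, adjusted p = 3.1e-05). Nanog, Pou5f1 and Sox2, which maintain pluripotency, were not called, with log2 changes of -0.09, -0.16 and -0.40 (adjusted p = 0.775, 0.471 and 0.325).

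Of 13984 genes, 655 were higher and 350 lower in Ring1B deficient cells, 356 and 119 of them by at least 2-fold. Large rises included Hoxa9 and genes of visceral endoderm and its uptake machinery, with Ttr at 209 ± 177 against 0.538 ± 0.113, Cubn at 413 ± 70 against 19.2 ± 12.9 and Dab2 at 578 ± 136 against 40.8 ± 11.6. Srgn, a proteoglycan of secretory granules, reached 1403 ± 247 against 58.7 ± 18.2. Large falls included imprinted transcripts. The imprinted list was not called by camera (adjusted p = 0.075), while fry, without a comparison with other genes, gave an adjusted p of 0.012 downward. Meg3 fell from 944 ± 298 to 43.8 ± 6.68 (log2 change -4.24, SE 0.50), Mest from 485 ± 108 to 27.8 ± 7.02 (-3.90, SE 0.22) and Rian from 362 ± 42.0 to 25.7 ± 3.45 (-3.58). Neurod1, a neuronal transcription factor, fell from 468 ± 7.25 to 83.8 ± 9.97.

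Among the lists, 18 of 24 primitive and visceral endoderm genes rose, 0 fell and 6 were not called, with a median log2 change of 2.10 (camera adjusted p = 1.4e-33) and 21 higher adjusted over the list alone. Of 26 Hox cluster genes, 19 rose and 0 fell (median 1.44, adjusted p = 2.4e-26; 20 higher adjusted over the list alone), among them Hoxc4 at 68.4 ± 4.26 and Hoxa10 (log2 change 3.05). Of 28 mesoderm and primitive streak genes, 15 rose and 0 fell (median 0.85, adjusted p = 1.2e-12; 17 adjusted over the list alone), with log2 changes of 2.86 for Tbx15 and 1.82 for Tbx20. These 3 list results held with an estimated correlation (adjusted p = 0.0042, 0.0042 and 0.0067). Of 26 germline genes, 14 rose and 1 fell (median 1.06, adjusted p = 1.1e-13; 0.095 with an estimated correlation; 16 and 2 adjusted over the list alone). Mael, of the piRNA pathway, went from 221 ± 43.9 to 1794 ± 148, Tex11 rose by 2.76 in log2, and Hsf2bp fell by 1.61 in log2. Of 25 neuroectoderm genes, 5 rose and 3 fell (median 0.34, adjusted p = 0.018; 0.30 with an estimated correlation; 10 and 3 adjusted over the list alone), with Zic1 at 154 ± 28.9 against 9.78 ± 1.42 and Pax6 at 40.5 ± 4.56 against 139 ± 49.9. That camera call was not made without Ring1B deficient replicate 1 (adjusted p = 0.0916).

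Of 20 trophoblast genes, 5 rose and 0 fell (median 0.47, adjusted p = 5.2e-04; 0.19 with an estimated correlation; 5 adjusted over the list alone), including Tfap2a with 1.20. Of 39 secreted signalling ligands, 5 rose and 1 fell (median 0.32, adjusted p = 0.0012; 0.084 with an estimated correlation; 10 and 1 adjusted over the list alone), with log2 changes of 1.93 for Bmp4 and -1.52 for Fgf17. Of 8 cyclin-dependent kinase inhibitors, Cdkn1c (1.15) and Cdkn2a (1.21) rose (median 0.26, adjusted p = 0.011; 0.24 with an estimated correlation; 3 adjusted over the list alone). Of 28 pluripotency genes, 2 rose and 4 fell (median -0.13, adjusted p = 0.031; 0.48 with an estimated correlation; 2 and 5 adjusted over the list alone), with Tfcp2l1 at 0.89, Pecam1 at -0.97 and Gdf3 at -0.91. Of 24 imprinted genes, 2 rose and 5 fell (median -0.07, adjusted p = 0.075; 3 and 6 adjusted over the list alone), and of 31 Polycomb complex members 4 rose and 1 fell (median -0.05 and mean 0.04, adjusted p = 0.79; 5 and 1 adjusted over the list alone). The DNA methylation and retroelement silencing list had a median of -0.18 (adjusted p = 0.019; 0.48 with an estimated correlation; 0 called adjusted over the list alone). The fibroblast and feeder cell markers, 2-cell-stage genes and housekeeping genes had 0 calls each, with camera adjusted p = 0.19, 0.34 and 0.38. The imprinted list was called without wild type replicate 2, Ring1B deficient replicate 1 or Eed deficient replicate 3 (adjusted p from 0.0256 to 0.0384), and the fibroblast list without Eed deficient replicate 3 (0.0318).

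Without Ring1B deficient replicate 2 the higher count was 429, and the lower count was 193, 201 and 157 without wild type replicate 3, Ring1B deficient replicate 2 and Ring1B deficient replicate 3. The camera calls of the pluripotency and DNA methylation lists were not made without wild type replicate 1, wild type replicate 3 or Ring1B deficient replicate 2 (adjusted p from 0.0709 to 0.208), nor that of the kinase inhibitors without wild type replicate 1 (0.0535).

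Eed deficient cells were compared with wild type for the same question about PRC2. The same endoderm regulators rose. Sox17 went from 14.1 ± 3.46 to 358 ± 32.6 (SD, n = 3, log2 change 4.26, SE 0.18), Gata6 from 22.6 ± 4.14 to 153 ± 23.8 (2.52) and Gata4 from 20.1 ± 4.59 to 78.1 ± 11.1 (1.74). Hoxa9 reached 107 ± 14.7 and Bmi1 reached 296 ± 12.6 against 85.4 ± 13.3. Pou5f1 fell from 2735 ± 294 to 1887 ± 56.8 (log2 change -0.53, adjusted p = 0.0061), while Nanog stayed at 1728 ± 52.1 against 1931 ± 330 and was not called.

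In all, 1509 genes were higher and 637 lower in Eed deficient cells, 767 and 130 of them by at least 2-fold. With every array centred on its median the split was 1123 higher and 1294 lower, and under quantile normalization it was 1348 and 665. Large rises included Ttr at 512 ± 583, Tex13b at 245 ± 56.8, Srgn at 1030 ± 81.4 and Cubn at 306 ± 141. Rhox6, of the X-linked Rhox cluster active in placenta, rose to 397 ± 142 against 22.1 ± 5.33, and Cyp26a1, which breaks down retinoic acid, rose to 212 ± 11.7 against 12.5. Meg3 fell to 107 ± 119 (log2 change -3.58), Rian to 43.2 ± 22.1 (-3.01) and Neurod1 to 82.5 ± 21.9 (-2.46).

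Of the primitive and visceral endoderm genes, 20 rose and 0 fell (median log2 change 2.48, adjusted p = 6.0e-26; 22 adjusted over the list alone), with Lama1 of the basement membrane at 759 ± 135 against 58.6 ± 10.1. Of the Hox cluster genes, 19 rose and 0 fell (median 1.54, adjusted p = 1.3e-18; 21 adjusted over the list alone). Of the mesoderm and primitive streak genes, 16 rose and 0 fell (median 0.98, adjusted p = 1.8e-11; 19 adjusted over the list alone), with Tbx15 at 58.6 ± 13.1 and Tbx20 at 71.3 ± 18.8. Of the trophoblast genes, 14 rose and 0 fell (median 1.06, adjusted p = 4.9e-11; 17 adjusted over the list alone), with the keratins Krt8 at 1705 ± 387 against 213 ± 133 and Krt18 at 2408 ± 969, and Rhox9 at 222 ± 86.3. Of the secreted ligands, 12 rose and 1 fell (median 0.63, adjusted p = 4.9e-05; 17 and 1 adjusted over the list alone), with log2 changes of 2.53 for Bmp2 and 2.12 for Wnt4. These 5 lists held with an estimated correlation (adjusted p = 0.0089, 0.0089, 0.0089, 0.023 and 0.026).

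Other lists were called by camera only with the preset correlation. By fry, kinase inhibitors (adjusted p = 0.0012) and fibroblast markers (0.049) moved 1 way. Pluripotency (0.12), germline (0.051), DNA methylation (0.15), 2-cell-stage (0.12) and housekeeping lists (0.070) did not reach 0.05 by fry. Fibroblast and feeder cell markers had 10 higher and 0 lower (median 0.88, adjusted p = 1.8e-06; 0.36 with an estimated correlation; 12 adjusted over the list alone), among them Timp3 at 210 ± 73.1 and Anxa1 at 1417 ± 548. In Eed deficient replicate 3 these markers lay a median of 1.29 in log2 above the other Eed deficient arrays, and 25 of 25 were higher there. Of the kinase inhibitors, 4 rose and 0 fell (median 0.59, adjusted p = 4.4e-04; 0.11 with an estimated correlation; 5 adjusted over the list alone), with log2 changes of 1.53 for Cdkn2b and 1.52 for Cdkn2a, genes of the locus that restrains cell cycle entry. Of the pluripotency genes, 1 rose and 5 fell (median -0.24, adjusted p = 0.0020; 0.36 with an estimated correlation; 1 and 6 adjusted over the list alone). Of the germline genes, 7 rose and 1 fell (median 0.43, adjusted p = 0.028; 0.52 with an estimated correlation; 9 and 1 adjusted over the list alone), a camera call not made without wild type replicate 1 or Eed deficient replicate 2 (adjusted p = 0.186 and 0.20). DNA methylation and retroelement silencing genes had 0 higher and 4 lower (median -0.27, adjusted p = 0.0032; 0.36 with an estimated correlation; 4 lower adjusted over the list alone), and without wild type replicate 1 the p was 0.0532. 2-cell-stage genes had 1 lower (median -0.59, adjusted p = 0.048) and housekeeping genes 1 higher and 1 lower (median -0.14, adjusted p = 0.044), both 0.36 with an estimated correlation. The 2-cell call was not made without wild type replicate 3, Ring1B deficient replicate 1 or 3, or Eed deficient replicate 1 or 2 (adjusted p from 0.0503 to 0.183). The housekeeping call was not made without wild type replicate 1 or 2 or Eed deficient replicate 1 or 3 (from 0.0532 to 0.129).

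Neuroectoderm genes (8 higher, 2 lower, median 0.33, adjusted p = 0.18; 10 and 3 adjusted over the list alone), Polycomb complex members (5 and 2, median -0.02, 0.82; 5 and 4 adjusted over the list alone) and imprinted genes (6 and 5, median 0.24 and mean -0.03, 0.82; 7 and 6 adjusted over the list alone) were not called as lists. Igf2, a paternally expressed growth factor, rose to 1090 ± 390 against 103 ± 65.5 and Plagl1 to 489 ± 90.7 against 91.6. Without wild type replicate 1, wild type replicate 3, Eed deficient replicate 2 and Eed deficient replicate 3 the lower count in Eed deficient cells was 424, 365, 397 and 332.

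**Figure D2:**
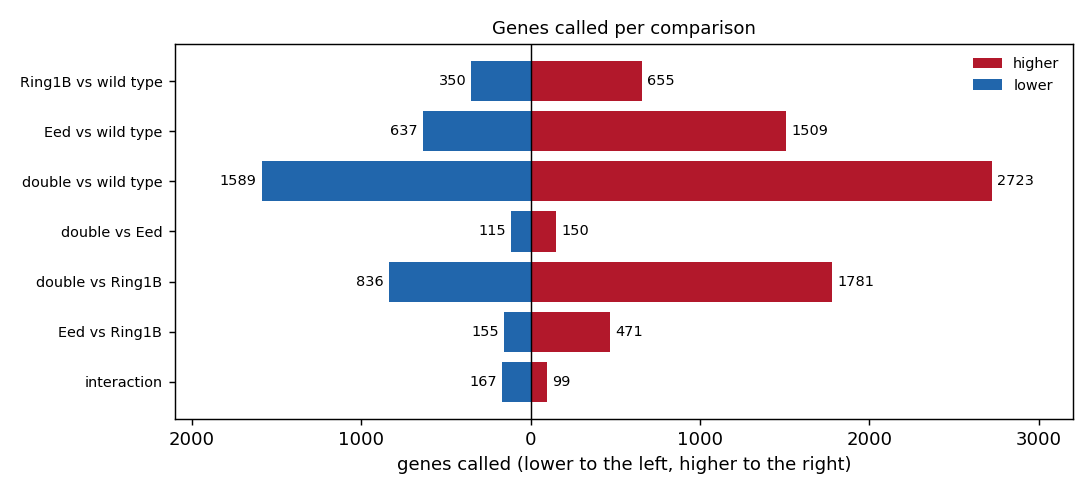
Number of called genes (adjusted p under 0.05, of 13984) for 7 contrasts, with bars to the right for higher and to the left for lower genes. The double deficient cells differed from wild type in 2723 higher and 1589 lower genes, against 150 and 115 from Eed deficient cells.

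Double deficient cells were compared with wild type to find how far the transcriptome shifts when both complexes are impaired. Sox17 reached 758 ± 87.4, Gata6 293 ± 18.9 and Gata4 156 ± 12.5 (SD, n = 3), log2 changes of 5.33, 3.44 and 2.69. Nanog went from 1931 ± 330 to 1096 ± 80.5 (log2 change -0.80, SE 0.13, adjusted p = 4.1e-04) and Pou5f1 from 2735 ± 294 to 1550 ± 148 (-0.82, SE 0.11, adjusted p = 1.3e-04). Ezh2, the catalytic subunit of PRC2, fell from 1338 ± 223 to 872 ± 42.2 (-0.60, adjusted p = 0.0036), whereas Suz12 (627 ± 59.5 against 732 ± 58.1) was not called. Sox2 fell to 1787 ± 382 against 2876 ± 74.1 (adjusted p = 0.022), a call not made without wild type replicate 3 or double deficient replicate 2 (adjusted p = 0.0646 and 0.10).

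The median of all genes was 0.105 higher in log2 in double deficient cells than in wild type and 0.114 higher than in Ring1B deficient cells. Log2 changes are printed with this shift included. Median centring takes out differences between array medians, which is not the same shift. It left the median log2 change of all genes at -0.0963 against wild type and -0.0755 against Ring1B deficient cells. In all, 2723 genes were higher and 1589 lower than in wild type, 1407 and 304 of them by at least 2-fold. With every array centred on its median the split was 1875 and 2934, and under quantile normalization it was 2206 and 1810. Large rises included Tex13b at 400 ± 37.4, Lama1 at 1301 ± 108, Cyp26a1 at 303 ± 14.3, and log2 changes of 4.72 for S100g, 4.32 for Hs3st1 and 4.19 for Col4a2. The Rosa26 transcript Gt(ROSA)26Sor fell from 1567 ± 369 to 128 ± 23.8, Mest to 31.7 ± 7.61 and Fgf17 from 175 ± 59.5 to 19.6 ± 6.43.

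Of the primitive and visceral endoderm genes, 21 rose and 0 fell (median log2 change 3.13, adjusted p = 1.3e-18; 22 adjusted over the list alone). Hox cluster genes had 23 higher and 0 lower (median 1.92, adjusted p = 9.2e-17; 25 adjusted over the list alone), and mesoderm and primitive streak genes 22 and 0 (median 1.17, adjusted p = 2.1e-10; 23 adjusted over the list alone). Trophoblast genes had 16 and 0 (median 1.49, adjusted p = 1.7e-08; 16 adjusted over the list alone), with Krt8 at 2272 ± 524 and Plac1 at 142 ± 41.0 against 14.3. Secreted ligands had 23 and 2 (median 0.74, adjusted p = 3.5e-05; 23 and 2 adjusted over the list alone). These 5 lists held with an estimated correlation (adjusted p = 0.012, 0.012, 0.012, 0.040 and 0.031).

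Pluripotency genes had 0 higher and 13 lower (median -0.52, adjusted p = 4.2e-06; 0.18 with an estimated correlation; 14 lower adjusted over the list alone), including Fgf4 with -1.08 and Gdf3 with -1.38. DNA methylation and retroelement silencing genes had 0 higher and 8 lower (median -0.44, adjusted p = 3.6e-04; 0.25 with an estimated correlation; 1 and 9 adjusted over the list alone), with Suv39h2 at -1.15 and Cbx5 at -1.07. Fibroblast and feeder cell markers had 21 higher and 0 lower (median 1.59, adjusted p = 2.7e-09; 0.25 with an estimated correlation; 21 adjusted over the list alone). Germline genes had 16 and 3 (median 0.97, adjusted p = 3.6e-04; 0.31 with an estimated correlation; 16 and 3 adjusted over the list alone), neuroectoderm genes 13 and 3 (median 0.87, adjusted p = 0.010; 0.25; 14 and 4 adjusted over the list alone) and kinase inhibitors 5 and 0 (median 0.70, adjusted p = 0.026; 0.25; 5 adjusted over the list alone). Imprinted genes (9 and 7, adjusted p = 0.61), Polycomb complex members (6 and 6, 0.19) and 2-cell-stage genes (2 and 0, 0.27) were not called as lists. Housekeeping genes had a median of -0.19 (adjusted p = 0.030; 0.25 with an estimated correlation), which was 0.01 under quantile normalization, and the call was not made without wild type replicate 2 or double deficient replicate 3 (adjusted p = 0.0704 and 0.0795). Without double deficient replicate 3 the lower count of all genes was 1017.

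Ring1B deficient and Eed deficient cells shared 516 higher and 162 lower genes, where independent lists of these sizes would share 70.7 and 15.9. Of the called genes, 5 went in opposite directions. The log2 changes correlated at r = 0.714 across genes, against 0.499 in simulations without effects, and their covariance was 0.186 against 0.0338. The 3 wild type arrays could not be divided into parts of 2, so part of the excess may come from the shared wild type arrays. Contrasts without shared arrays also overlapped. Ring1B deficient against wild type and double against Eed deficient shared 51 higher genes (independent lists 7.03) and 15 lower (2.88), with r = 0.150. Eed deficient against wild type and double against Ring1B deficient shared 718 higher (192) and 211 lower (38.1), with r = 0.486. Per the labels the double line came from Eed deficient cells, so any line differences it inherited would add to this last overlap.

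Of the 516 genes higher in both single mutants, 485 were also higher in the double deficient cells. Their median log2 change was 1.11 in Ring1B deficient, 1.30 in Eed deficient and 1.62 in double deficient cells. Of the 162 lower genes, 146 were also lower in double deficient cells, with medians of -0.84, -0.89 and -0.98. Both sets were picked on their single changes against the same wild type arrays, which enlarges the single medians. The double deficient medians and counts use these wild type arrays too, so they are not an independent check.

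Double deficient cells were compared with Eed deficient cells, the line they were derived from, to ask about losing Ring1B where Eed was already absent. This contrast joins the loss of Ring1B with any other difference between the parent and the daughter line. Some germline and endoderm genes rose, 8 of 26 and 4 of 24, while 2 germline genes fell. Neither list call held with an estimated correlation (adjusted p = 0.28 and 0.27). Mael rose from 432 ± 65.9 to 1185 ± 133 (SD, n = 3, log2 change 1.45, SE 0.16), Tex11 from 138 ± 14.4 to 387 ± 42.7, and Sox17 from 358 ± 32.6 to 758 ± 87.4 (1.07, adjusted p = 0.0095). Gata6 rose from 153 ± 23.8 to 293 ± 18.9 and Gata4 from 78.1 ± 11.1 to 156 ± 12.5, while Nanog fell from 1728 ± 52.1 to 1096 ± 80.5 (-0.66) and Ezh2 from 1489 ± 119 to 872 ± 42.2 (-0.77). These last 4 calls depended on single arrays. Gata6 was not called without Eed deficient replicate 2 or any double deficient array (adjusted p from 0.0629 to 0.110), and Gata4 without Eed deficient replicate 1 or 3 or any double deficient array (from 0.0550 to 0.119). Nanog was not called without Eed deficient replicate 1 or 2 or any double deficient array (from 0.0559 to 0.108), and Ezh2 without Eed deficient replicate 1 or double deficient replicate 1 or 3 (from 0.0517 to 0.0606). Pou5f1 was not called (log2 change -0.29, adjusted p = 0.199).

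In all, 150 genes were higher and 115 lower in double than in Eed deficient cells, 98 and 32 of them by at least 2-fold. The split was 127 and 209 with every array centred on its median and 150 and 189 under quantile normalization. The largest rises included Rarres1, a membrane protein induced by retinoids, at 152 ± 51.9 against 15.4 ± 7.59, Arg2 at 100 ± 27.3 against 19.4 ± 3.54, and Sycp1, of the synaptonemal complex, at 126 ± 27.8 against 27.5 ± 9.49. Gt(ROSA)26Sor fell from 1408 ± 260 to 128 ± 23.8 (-3.40, SE 0.18), Mest from 326 ± 49.6 to 31.7 ± 7.61 (-3.18, SE 0.22) and Pla2g1b from 300 ± 38.7 to 57.5 ± 11.8 (-2.30).

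No list call in this contrast held with an estimated correlation, where the adjusted p of the lists called at the preset value ran from 0.27 to 0.41. At the preset value germline genes had 8 higher and 2 lower (median 0.50, adjusted p = 2.0e-05; 13 and 2 adjusted over the list alone) and Hox cluster genes 1 and 0 (median 0.48, 2.8e-05; 3 and 0 adjusted over the list alone). Endoderm genes had 4 and 0 (median 0.40, 3.2e-04; 10 and 0 adjusted over the list alone), neuroectoderm genes 2 and 0 (median 0.37, 3.2e-04; 3 and 0) and pluripotency genes 0 and 1 (median -0.31, 1.1e-04; 0 and 6). Mesoderm and primitive streak genes had 0 calls (median 0.27, 0.0065). Fibroblast and feeder cell markers had 0 calls over all genes and 11 higher adjusted over the list alone (median 0.66, 2.6e-06). Without Eed deficient replicate 3, S100a4 (0.00705), Postn (0.00318), Col3a1 (0.00493) and Col5a2 (0.00893) of these were called. The 2-cell-stage genes had 2 higher (median 1.23, 3.2e-04; 3 adjusted over the list alone). DNA methylation and retroelement silencing genes had 2 lower (median -0.18, 0.0075), a call not made without Eed deficient replicate 1 or double deficient replicate 2 (0.126 and 0.156). Trophoblast (0.18), Polycomb (0.13), imprinted (0.13), kinase inhibitor (0.38) and housekeeping lists (0.36) were not called. The trophoblast list was called without double deficient replicate 1 (0.0294), the Polycomb list without Eed deficient replicate 2 (0.0273) and the imprinted list without Eed deficient replicate 3 (0.032). The ligand list was called at an adjusted p of 0.0497, and not without wild type replicate 1, Ring1B deficient replicate 2, Eed deficient replicate 1 or 2, or double deficient replicate 2 or 3 (adjusted p from 0.0520 to 0.233).

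Without any 1 array of these genotypes except Eed deficient replicate 3 the counts of this contrast fell by more than 1.5 times. The higher count was 55, 63, 43, 70 and 25 without Eed deficient replicates 1 and 2 and double deficient replicates 1, 2 and 3, and the lower count was 33, 53, 32, 69 and 16 without the same arrays.

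Double deficient cells were compared with Ring1B deficient cells, which lack Ring1B alone. Per the labels the double line came from Eed deficient cells, so this contrast joins the loss of Eed with any difference between the lines. Igf2 rose from 214 ± 66.9 to 1570 ± 693 (SD, n = 3, log2 change 2.80, SE 0.40), Krt8 from 605 ± 220 to 2272 ± 524 (1.93) and Cdkn2b from 69.3 ± 6.30 to 340 ± 6.85 (2.22). Sox17, Gata6 and Gata4 were higher by 1.94, 1.18 and 1.06 in log2. Nanog and Pou5f1 were lower, with log2 changes of -0.72 (adjusted p = 0.0023) and -0.66 (adjusted p = 0.0017).

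In all, 1781 genes were higher and 836 lower, 839 and 119 of them by at least 2-fold. The split was 1110 and 1889 with every array centred on its median and 1300 and 954 under quantile normalization. Fibroblast and feeder cell markers gave 20 higher and 0 lower of 25 (median 1.96, adjusted p = 5.7e-14; 0.25 with an estimated correlation; 23 adjusted over the list alone), with Col1a2 at 752 against 132, Timp3 at 398 ± 75.3 against 56.4 ± 14.9 and S100a4 at 951 ± 196 against 167. The largest rises of the contrast included the lysozyme gene Lyz1, at 411 ± 101 against 22.6, and Rarres1 (log2 change 4.12). Nrp1 was also among them, at 464 ± 105 against 51.1 ± 22.7. Iqcg fell from 108 ± 14.8 to 5.66 ± 3.52 and Gt(ROSA)26Sor from 1644 ± 30.8 to 128 ± 23.8.

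No list call held here with an estimated correlation, where the adjusted p of the lists called at the preset value ran from 0.25 to 0.42. At the preset value trophoblast genes had 10 higher and 0 lower (median 0.80, adjusted p = 1.0e-05; 13 and 0 adjusted over the list alone), endoderm genes 13 and 1 (median 0.87, 3.7e-04; 13 and 1), mesoderm genes 8 and 0 (median 0.55, 0.0042; 8 and 0) and Hox cluster genes 6 and 0 (median 0.41, 0.0096; 8 and 0). Ligands had 12 and 2 (median 0.32, 0.0087; 17 and 2 adjusted over the list alone) and imprinted genes 9 and 2 (median 0.38, 0.0087; 11 and 3), with Plagl1 at 688 ± 25, Peg3 at 1.97 and Dlk1 at 2.11 in log2. Pluripotency genes had 0 and 5 (median -0.31, 1.8e-04; 0 and 5 adjusted over the list alone), DNA methylation genes 0 and 4 (median -0.24, 0.0086; 1 and 4) and germline genes 3 and 5 (median -0.42, 0.012; 4 and 5), the last not called without double deficient replicate 3 (0.0975). Neuroectoderm (0.064), Polycomb (0.12), kinase inhibitor (0.51), 2-cell-stage (0.055) and housekeeping lists (0.057) were not called. The 2-cell-stage list was called without wild type replicate 3, Ring1B deficient replicate 1 or 3, or double deficient replicate 1 or 2 (from 0.0189 to 0.0435). The neuroectoderm (0.0208 and 0.0354) and housekeeping lists (0.0166 and 0.0227) were called without Ring1B deficient replicate 1 or double deficient replicate 2. Without Ring1B deficient replicate 3 and double deficient replicate 3 the higher count of all genes was 1095 and 982. The lower count was 542, 480, 445 and 343 without Ring1B deficient replicate 2, Ring1B deficient replicate 3, double deficient replicate 1 and double deficient replicate 3.

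**Figure D3:**
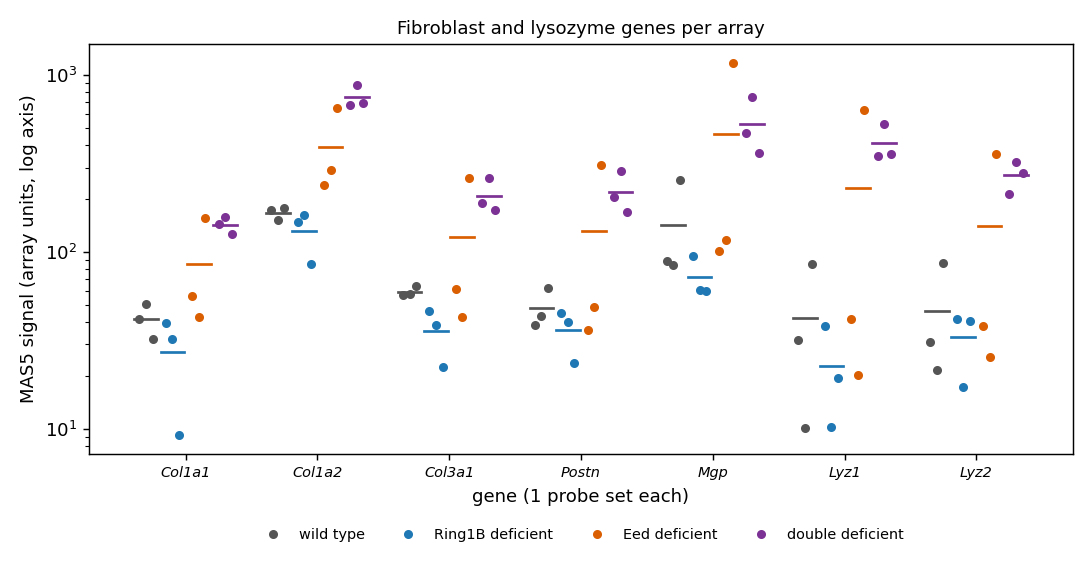
MAS5 signal (log axis) of 5 fibroblast genes and the lysozyme genes Lyz1 and Lyz2 in each of the 12 arrays, grouped by genotype. Lyz1 was 631 in Eed deficient replicate 3 against 41.6 and 20.2 in the other Eed deficient arrays, and averaged 411 in double deficient cells.

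The single mutants were compared with each other for genes that depend more on either complex. Mest was 326 ± 49.6 in Eed deficient and 27.8 ± 7.02 in Ring1B deficient cells (SD, n = 3, log2 change 3.35, SE 0.22). Rhox6 (397 ± 142 against 53.7 ± 30.8) and Rhox9 (222 ± 86.3 against 19.8 ± 6.99) were also higher in Eed deficient cells. Of 26 germline genes 8 were lower there and 2 higher (adjusted p = 0.35 for the list with an estimated correlation), with Mael at 432 ± 65.9 against 1794 ± 148 (-2.05, SE 0.16), Ddx4 at 313 ± 82.4 against 895 ± 68.8 (-1.53) and Mov10l1 at 69.4 ± 18.6 against 227 ± 21.7 (-1.67). Gata6 and Gata4 were not called, with 0.26 and 0.11 (adjusted p = 0.491 and 0.835).

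In all, 471 genes were higher and 155 lower in Eed than in Ring1B deficient cells, 247 and 32 of them by at least 2-fold. The split was 270 and 264 with every array centred on its median, and 1142 and 564 with the replicate number as a block. No list call held with an estimated correlation (adjusted p from 0.27 to 0.47). At the preset value fibroblast and feeder cell markers had 8 higher and 0 lower (median 1.09, adjusted p = 5.5e-13; 19 and 0 adjusted over the list alone), germline genes 2 and 8 (median -0.76, 3.5e-11; 2 and 15), and trophoblast genes 6 and 0 (median 0.60, 2.5e-07; 12 and 0). The fibroblast markers lay a median of 1.29 in log2 higher in Eed deficient replicate 3 than in the other Eed deficient arrays. That array carried part of their rise. Postn was 36.5, 48.7 and 309 in Eed deficient replicates 1, 2 and 3, against a mean of 36.4 in Ring1B deficient cells. Col1a2 was 238, 292 and 650 against 132, higher in each of these arrays. Imprinted genes had 5 and 0 (median 0.10, 0.016; 7 and 2 adjusted over the list alone), not called without Eed deficient replicate 3 (0.0529), and endoderm genes 5 and 0 (median 0.42, 0.020; 8 and 0), not called without Ring1B deficient replicate 1 or Eed deficient replicate 2 (0.172 and 0.260). The other 10 lists were not called, with adjusted p from 0.12 for the pluripotency list to 0.95 for the Polycomb list. Of these, the pluripotency (0.0056), kinase inhibitor (0.00856) and DNA methylation lists (0.0406) were called without Eed deficient replicate 1, the ligand list without Eed deficient replicate 2 (0.0337) and the housekeeping list without Ring1B deficient replicate 1 (0.0381). The higher count was 144, 291 and 170 without Ring1B deficient replicate 3, Eed deficient replicate 2 and Eed deficient replicate 3. The lower count was 103, 86 and 43 without Ring1B deficient replicates 1, 2 and 3, 92, 86 and 49 without Eed deficient replicates 1, 2 and 3, and 98 without double deficient replicate 1.

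The interaction asked whether the change from losing Ring1B differed between cells with and without Eed. With no second line of any genotype described in the labels, the interaction also holds any differences between lines. It was positive for 99 genes and negative for 167. Hoxa9 rose by 4.22 from wild type to Ring1B deficient cells but was 107 ± 14.7 in Eed deficient and 123 ± 16.5 in double deficient cells (SD, n = 3), an interaction of -4.03 (SE 0.33). Wild type Hoxa9 was near the background, so the size of both values depends on the added value, with an interaction of -4.91 when 1 was added and -3.44 when the added value was doubled. Srgn (-4.73), Cubn (-3.98), Dab2 (-3.81) and Bmi1 (-1.19) gave the same sign. Meg3, low in both single mutants, was not lower still in double deficient cells, with 132 ± 13.3 against 107 ± 119 in Eed deficient cells (interaction 5.07). It was called higher than in Eed deficient cells without Eed deficient replicate 3 (adjusted p = 0.00467). Both single falls of Meg3 added together would end below the lowest value possible after adding 5, so the positive sign was fixed in advance. The Hox cluster list (10 negative, 0 positive, median -1.14, adjusted p = 5.9e-15; 0 and 15 adjusted over the list alone) and the endoderm list (11 negative, 0 positive, median -1.54, 4.7e-24; 0 and 20) held with an estimated correlation (0.025 and 0.014). Without Ring1B deficient replicate 3, double deficient replicate 1 and double deficient replicate 3 the positive count was 59, 55 and 31 and the negative count 109, 80 and 62.

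Genes called in the double deficient cells against each of the other 3 genotypes numbered 106 higher and 59 lower. Of the higher genes, 31 were also higher in Ring1B deficient cells than in wild type, 49 in Eed deficient cells, 30 in both, and 53 were called in neither direction in either. Of the lower genes, 9 were also lower in Ring1B deficient cells, 16 in Eed deficient cells, 7 in both, and 40 were called in neither direction in either. The smallest of the 3 changes was 2.96 for Rarres1, 2.13 for H2-Aa, 2.04 for Arg2 and Fam163a, and 1.88 for the neurofilament gene Nefm. It was -3.40 for Gt(ROSA)26Sor and -1.97 for Pla2g1b. Sox17, Gata6, Gata4 and Lama1 of the endoderm list were in the higher set, and Nanog and Ezh2 in the lower set. The higher count was 39, 40 and 161 without Eed deficient replicates 1, 2 and 3 and 25, 40 and 11 without double deficient replicates 1, 2 and 3. The lower count was 21 and 33 without Eed deficient replicates 1 and 2, and 19 and 9 without double deficient replicates 1 and 3.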

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

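The tests of the Meg3 group, the regroupings of residuals, the fits without genes raised in Eed deficient replicate 3 and the fit without the 4 arrays numbered 2 were chosen after the results were seen.

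In the limma model 99 genes had a positive and 167 a negative interaction, where the change linked to losing Ring1B differed between cells with and without Eed. Each of these interactions is a difference between changes that was itself tested. The labels describe no second line of any genotype, so differences between lines cannot be told apart from an effect of losing Ring1B. Of 100 regroupings (splits) of the 12 arrays into 4 sets of 3, the real grouping included, 2 gave as many genes as the real 266, and the highest other count was 407. These sets mix genotypes, so few calls follow by construction and this says nothing about chance. In a test of chance with both main effects kept, the residuals of a model without interaction were regrouped instead. Here 3 of 100 regroupings, the real one included, gave as many as the real 266, a share under 0.05. The replicate 2 arrays deviate together, so the residuals are not interchangeable and this share does not exclude chance. The highest other counts, 1415 and 543, point to a structure of the samples. They came from 2 of the 5 regroupings with all 4 replicate 2 arrays on 1 side of the interaction, and the other 3 of these gave 168, 10 and 0, so that arrangement alone does not account for them. Apart from these 5 and the real grouping all gave 0. The real grouping has 2 on each side. With the replicate number as a block the counts were 541 positive and 719 negative.

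The largest negative interactions were those of Ttr (interaction -5.38), Srgn (-4.73), Alox12b (-4.26), Hoxa9 (-4.03), Cubn (-3.98), Dab2 (-3.81), Gt(ROSA)26Sor (-3.50) and Spink1 (-3.42). Ttr, Srgn, Hoxa9, Cubn and Dab2 were called higher than wild type in all 3 mutants, while Gt(ROSA)26Sor was high in wild type and both single mutants and low in double deficient cells. Ttr, Alox12b and Hoxa9 were near the background in wild type (0.538, 6.40 and 4.69), so the sizes of their interactions, and their place among the largest, depend on the added value. With that value doubled they were -4.52, -3.37 and -3.44, and Ttr was no longer called (adjusted p = 0.0539). The Ttr call also ended without any wild type or double deficient array or Ring1B deficient replicate 1 or 2 (adjusted p from 0.0503 to 0.0763). The Alox12b call ended without wild type replicate 1 or 2, any Ring1B deficient array, Eed deficient replicate 1 or 2 or double deficient replicate 1 or 3 (from 0.0510 to 0.0981). The Spink1 call ended without wild type or Ring1B deficient replicate 2 or 3 or any double deficient array (from 0.0536 to 0.0936).

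The list medians followed these genes, with -1.54 for primitive and visceral endoderm, -1.14 for Hox cluster genes, -0.56 for mesoderm and primitive streak genes, -0.60 for germline genes and -0.52 for kinase inhibitors. The last 3 had adjusted p = 6.1e-06, 7.9e-06 and 0.0065 at the preset correlation and 0.066, 0.32 and 0.29 with an estimated one. Gata6 had an interaction of -1.33 (adjusted p = 0.016), which was not called without double deficient replicate 1 or 3 (0.0536 and 0.0548), and Gata4 of -0.68 was not called (adjusted p = 0.213). Pluripotency, neuroectoderm, trophoblast, Polycomb, ligand, DNA methylation and housekeeping lists were not called, with adjusted p = 0.38, 0.98, 0.055, 0.13, 0.23, 0.98 and 0.98. The trophoblast list was called without wild type replicate 2, Ring1B deficient replicate 3, Eed deficient replicate 1 or double deficient replicate 2 or 3 (from 0.00442 to 0.0481), and the Polycomb list without wild type replicate 1 or Eed deficient replicate 2 (0.0456 and 0.0361).

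Among the 8 largest positive interactions, Meg3 (5.07), Rian (4.35) and Nxf3 (3.48) were called lower than wild type in both single mutants. Nxf3 was not called in double deficient cells against wild type (66.2 ± 17.9 against 120 ± 38.6). For Meg3 and Rian both falls added together would end below the lowest value possible after adding 5. The positive sign of their interactions was therefore fixed in advance. Rarres1 (3.13) rose in double deficient cells. Gm20767 (3.20), BC080696 (3.15) and AF067061 (2.94) were called lower in Eed deficient cells than in wild type and higher in double than in Eed deficient cells, and Spesp1 (2.71) was called higher in double than in each single mutant. The AF067061 call ended without double deficient replicate 3 (adjusted p = 0.0674), and the Spesp1 call without wild type replicate 1 or 3, Ring1B deficient replicate 1 or 2, Eed deficient replicate 1 or 3 or double deficient replicate 2 or 3 (from 0.0576 to 0.138). Imprinted genes had a median interaction of 0.46, fibroblast and feeder cell markers of 1.15 and 2-cell-stage genes of 1.60, with adjusted p = 0.0099, 6.1e-06 and 4.8e-04 at the preset correlation and 0.30, 0.41 and 0.21 with an estimated one.

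The fibroblast and feeder cell markers moved in 2 places. They lay 1.29 higher in Eed deficient replicate 3 than in the other Eed deficient arrays, and 1.96 higher in double than in Ring1B deficient cells, with 25 of 25 markers higher in both. Between-array scaling is argued against, since quantile normalization kept 102% and 104% of these medians. RNA from other cells such as feeder fibroblasts with macrophages stays open. In double against Ring1B deficient cells macrophage markers were 0.826 higher (10 of 13 higher, exact sign test p = 0.0923, and 0.573 under quantile normalization). This met the limits set beforehand for this explanation. In Eed deficient replicate 3 they were only 0.205 higher (9 of 13), which lies between those limits and leaves it open there. A rise of the brightest markers was asked for in addition and was not part of those limits. The 5 brightest macrophage markers over all arrays went both ways in double against Ring1B deficient cells. Csf1r was called higher (79.0 against 31.3), Laptm5 was called lower (104 against 229), and Cd68 (41.5 against 80.7), Coro1a (76.9 against 64.2) and Slc11a1 (41.3 against 47.0) were not called. Wild type already had 149, 75.5, 93.9 and 65.1 for the last 4, so a small share of other cells could be hidden in them. C1qb, Ctss, Pf4 and Ms4a7, macrophage genes outside the list, were chosen after their values were seen. They averaged 30.8, 49.5, 65.1 and 38.3 in double deficient against 6.65, 7.49, 15.8 and 2.36 in Ring1B deficient cells. In Eed deficient replicate 3 they were 43.2, 56.2, 92.1 and 41.6. The other Eed deficient arrays averaged 9.65, 8.4, 20.04 and 4.02. All rose with the fibroblast markers, but being picked by their values they cannot decide the source.

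Among the most abundant markers, Vim averaged 2163 and Col1a2 752 in double deficient cells, and Lyz1, which is in neither list, was 631 and Mgp 1171 in Eed deficient replicate 3. Wild type arrays already had signals above 100 for 14 of 25 fibroblast and 1 of 13 macrophage markers, and 0 of either are in another fixed list. The fibroblast interaction of 1.15 was called at the preset correlation (adjusted p = 6.1e-06). Without the 319 genes at least 1.5-fold higher in Eed deficient replicate 3 it was 0.90 and not called (0.071), and without the 98 genes at least 2-fold higher it was 0.60 and called (0.0072). Both fits leave out markers by the rise in question, so they decide nothing about its source. An effect of genotype on these genes in double deficient cells may also be at work, and it stays untested, because genotype and culture go together in these arrays.

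Meg3, Rian and Mirg, neighbouring transcripts of a maternally expressed imprinted cluster, were lower in both single mutants than in wild type. A fault of single probe sets is argued against, since 100% of their 8 well-measured probe sets, of 17 tested, were at least 2-fold lower in both. More feeder RNA in the wild type arrays is argued against too, since fibroblast and macrophage markers together were only 0.194 lower in Ring1B deficient (-0.194) and 0.763 higher in Eed deficient cells, where this explanation needed at most -1. An effect of either mutation, and a change of this locus in the line used for each genotype, may each give such a fall and stay untested, because the labels describe no second line of any genotype. Meg3 was 39.9, 35.7 and 244 in the Eed deficient arrays, with the high value in replicate 3, where the fibroblast markers were also high.

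Probe sets absent from the gene annotation carried signal that no gene count includes. Of 4105 such probe sets tested, 34 were higher in Ring1B deficient, 88 in Eed deficient and 294 in double deficient cells than in wild type, and 32, 39 and 162 were lower.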

How the results depend on the processing

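The fits without the 4 arrays numbered 2 and without genes raised in Eed deficient replicate 3 were chosen after the data were seen. No called list or named gene was called in the reverse direction under any alternative run, and 1 of the 4312 genes called in double deficient cells against wild type was with the mean of all probe sets per gene. Of the values of named genes under all alternatives, 14326 stayed on their side of the threshold, 249 passed it and 556 no longer did. For gene lists these were 2750, 55 and 128, and 52 of the 128 came from the estimated correlation. The housekeeping median in double deficient cells against wild type was -0.19 and became 0.01 under quantile normalization, where the list was no longer called. Causes were not tested unless given.

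Below, counts are higher and lower genes. The added value, both filters, the choice of probe sets and the removal of genes raised in Eed deficient replicate 3 kept every count of called genes within 1.5 times. Median centring gave a lower count of 1294 for Eed deficient against wild type, 2934 for double deficient against wild type and 209 for double against Eed deficient. It gave 1110 and 1889 for double against Ring1B deficient, 270 and 264 for Eed against Ring1B deficient, and 140 lower beyond all other genotypes. Quantile normalization gave 189 lower for double against Eed deficient and 107 lower beyond all others. Median centring moves the signals of arrays with higher medians down, which by construction lowers higher and raises lower counts.

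With array weights the counts were 1135 lower (Eed deficient against wild type), 647 and 581 (double against Eed deficient), 1348 lower (double against Ring1B deficient), 868 and 279 (Eed against Ring1B deficient), 275 and 344 (interaction) and 389 and 292 (beyond all others). Without the intensity trend they were 74 lower for double against Eed deficient and 37 lower beyond all others. With only the compared groups in the fit, and so fewer arrays, they were 396 and 166 (Ring1B deficient against wild type), 986 and 311 (Eed deficient against wild type), 69 lower (double against Eed deficient), 186 and 45 (Eed against Ring1B deficient) and 35 lower beyond all others.

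A minimum change of 2-fold, which by its construction keeps fewer genes, gave 356 and 119 for Ring1B deficient, 767 and 130 for Eed deficient and 1407 and 304 for double deficient cells against wild type. It gave 98 and 32 for double against Eed deficient, 839 and 119 for double against Ring1B deficient, 247 and 32 for Eed against Ring1B deficient, and 59 and 15 beyond all others. Without the 4 arrays numbered 2, and so with fewer arrays, the counts were 224 lower (Ring1B deficient against wild type), 56 and 57 (double against Eed deficient), 291 and 74 (Eed against Ring1B deficient), 49 and 102 (interaction) and 35 and 39 (beyond all others).

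With the replicate number as a block the counts were 1276 and 948 for Ring1B deficient, 2295 and 1493 for Eed deficient, and 2410 lower for double deficient cells, each against wild type. They were 655 and 648 for double against Eed deficient, 2721 and 1652 for double against Ring1B deficient, 1142 and 564 for Eed against Ring1B deficient, 541 and 719 for the interaction, and 457 and 355 beyond all others. Outside Eed against Ring1B deficient the numbers were not taken to pair the samples, since arrays numbered 3 correlated weakly, though arrays numbered 2 deviated together. Same-numbered arrays there correlated at 0.377, 0.456 and 0.0663 (Ring1B deficient and wild type), 0.431, 0.450 and 0.0983 (Eed deficient and wild type), 0.245, 0.265 and -0.0478 (double and wild type), 0.304, 0.409 and 0.0585 (double and Eed deficient) and 0.164, 0.397 and 0.0686 (double and Ring1B deficient). In these, 5, 5, 4, 5 and 2 of 6 arrays correlated best with their own number. The block changed no list call for Eed against Ring1B deficient.

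With each array left out in turn, higher and lower counts ran from 429 to 688 and 157 to 362 for Ring1B deficient against wild type, 1012 to 1559 and 332 to 685 for Eed deficient against wild type, and 2005 to 2782 and 1017 to 1650 for double deficient against wild type. They ran from 25 to 204 and 16 to 146 for double against Eed deficient, 982 to 1895 and 343 to 908 for double against Ring1B deficient, and 144 to 529 and 43 to 162 for Eed against Ring1B deficient. The ranges were 31 to 137 and 62 to 183 for the interaction and 11 to 161 and 9 to 77 beyond all others.

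For the 6 contrasts of 3 against 3 arrays, 1 of the 10 splits, the real one, gave as many called genes. The real counts were 1005, 2146 and 4312 for Ring1B, Eed and double deficient cells against wild type, 265 and 2617 for double against Eed and against Ring1B deficient, and 626 for Eed against Ring1B deficient, and the highest other count was 0 in each. These splits are too few for a share under 0.05. For Eed against Ring1B deficient, 4 splits part 3 pairs, and the highest of the others among them was 0. For genes beyond all others, 2 of 100 regroupings of the 12 arrays, the real one included, gave as many as the real 165, with 297 the highest other. These sets mix genotypes, so few calls follow by construction and this says nothing about chance. Signal over background limits genes such as Hoxa9 and Ttr, which were near the background in wild type.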

Other observations

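The test of RNA degradation was chosen after the result was seen, as were the genes named as chosen so.

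The 2-cell-stage gene Usp17la was 244 ± 94.0 in double deficient cells against 89.8 ± 52.4 in wild type, 95.9 ± 21.7 in Ring1B deficient and 31.8 ± 2.18 in Eed deficient cells (SD, n = 3), and Pramel7 was 34.0 ± 12.4 against 10.2 ± 4.20, 5.92 ± 4.22 and 8.80 ± 0.80. The Pramel7 call against Eed deficient cells was not made without any Eed or double deficient array or Ring1B deficient replicate 1 (adjusted p from 0.0560 to 0.201).

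The class II histocompatibility gene H2-Aa reached 95.5 ± 24.3 in double deficient cells against 7.42 ± 2.58 in wild type. Genes of the same pathway, chosen after their values were seen, did not all follow. H2-Eb1 was 1.28 higher than in Eed deficient cells (adjusted p = 0.035), H2-Ab1 was not called there (0.56, adjusted p = 0.167), and Cd74 was not called against wild type (0.15, adjusted p = 0.604).

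Gt(ROSA)26Sor, the transcript of a locus much used for transgene insertion, was 1567 ± 369, 1644 ± 30.8, 1408 ± 260 and 128 ± 23.8 in wild type, Ring1B deficient, Eed deficient and double deficient cells. The Y-linked Eif2s3y was 216 ± 75.4, 119 ± 20.8, 333 ± 105 and 63.8 ± 16.5 in the same order, and the Y-linked Uba1y, chosen after its values were seen, was 73.7 ± 11.2, 34.0 ± 6.65, 56.8 ± 21.3 and 11.1 ± 3.43. Mest was 485 ± 108, 27.8 ± 7.02, 326 ± 49.6 and 31.7 ± 7.61, low in both genotypes that lack Ring1B. No explanation of these values was tested.

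The replicate 2 arrays deviated together in all 4 genotypes. Against the other arrays of their genotype, 168 genes were higher and 140 lower by at least 0.5 in log2 in every genotype, and the first component of the deviations from group means held 39.6% of the variance. Genes chosen after their values were seen included Spry4 (-1.40 to -2.23), Gbx2 (-1.34 to -2.55), Klf2 (-1.10 to -1.56) and Nr0b1 (-1.06 to -2.0), and upward Txnip (1.10 to 1.39) and Ppp1r3c (1.30 to 1.83). The pluripotency list, fixed beforehand, had its lowest median in replicate 2 of all 4 genotypes (-0.117, -0.336, -0.291 and -0.380 in wild type, Ring1B, Eed and double deficient cells, against the other arrays of the genotype), and the endoderm list its highest (0.182, 0.316, 0.264 and 0.144). RNA degradation stays open, since the 2 controls disagree. The 3' over 5' ratio was highest in replicate 2 in 0 of 4 genotypes for Gapdh and in 3 of 4 for beta-actin. The signal of the Cre hybridisation control was highest in replicate 2 in 4 of 4 genotypes (chance 0.0123 if every array is equally likely), so a shared difference in hybridisation or labelling stays open, and it was not tested on the genes. A different growth state of the cultures is another candidate explanation. ERK target and ribosome biogenesis genes, classes picked because related genes had been seen, had pooled medians of -0.204, -0.276, -0.408 and -0.318 in replicate 2 of wild type, Ring1B, Eed and double deficient cells, where the limit was -0.2 in every genotype, so wild type only just met it. The design names no biological group that sets replicate 2 apart, so no biological explanation beyond this was tested.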
